A study of Arabidopsis thaliana with 24 samples.

How the data were processed

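The deposited table gave 38088 genes in 24 columns, plus 1 line without values that was left out. The submitters' processing notes name alignment with Bowtie to TAIR10 and give no version. The tool that assigned fragments to genes, the gene annotation and any scaling between libraries are not given in the sources used here. That the values are FPKM as deposited by the authors was inferred from the values themselves: they are not whole numbers, and after multiplication by transcript length the low ones fall on steps of 1 fragment, so that fragments were counted per gene and divided by transcript length and library size before deposition. Among low values, 74.7% to 85.2% per library lay within 0.1 of a whole number of fragments, which gave the implied depth.

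Before the data were examined, a count-based test had been planned for a table of raw counts, with a stated fallback for normalized values. The fallback was used: limma-trend with robust empirical Bayes on log2(FPKM + 1), with genes of at least 1 FPKM in at least 3 libraries (20964 genes, 55.0% of the table) and the 8 groups of genotype, time and fraction in 1 fit with 16 residual degrees of freedom. No further scaling was applied. Folds on this scale understate the change of genes with low values. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

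Column names were read as W for wild type, d for dcp5-1, 0 and 15 for minutes, the suffix IP for polysomal RNA and no suffix for total RNA. The table does not define IP. No label ties the column numbers 0 to 2 to the replicate numbers of the sample titles. The ecotype labels of the dcp5-1 samples run from Col-1 to Col-12, which looks like a spreadsheet fill, and dcp5-1 was compared with Col-0 as the genotype labels give it. The TAIR10.1 annotation, which may differ from the authors' build, was used for symbols, transcript lengths, GC content and positions only, and matched 99.2% of the IDs.

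The 15 comparisons were T15 against T0 in each genotype, dcp5-1 against Col-0 at each time, and the difference of the 2 NaCl responses, each in total RNA, polysomal RNA and polysome association (the change in polysomal minus that in total RNA). A gene changed when its Benjamini-Hochberg adjusted p from limma was below 0.05 over all genes tested. Median standard errors were 0.0873 for a comparison within 1 fraction, 0.123 for association or a difference of responses, and 0.175 for the difference in association. Each SE uses the spread of the gene pooled over all groups of the fit, and the libraries named beside it are those compared.

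Gene lists fixed before the data were examined were rapid stress-inducible regulators, ABA and osmotic stress, sodium transport and osmosensing, mRNA decapping and decay, stress granule RNA-binding proteins, seed storage and late embryogenesis, cytosolic ribosomal proteins, translation factors, nuclear photosynthesis genes, root-expressed genes, heat shock and unfolded protein response, auxin response and cell expansion, and aquaporins, together with chloroplast-encoded and mitochondrion-encoded genes. Each list was tested with camera from limma with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists of a comparison. Members were also counted with the adjustment over the list alone.

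Genes were named by a rule fixed beforehand: DCP5; per comparison the 5 largest positive and 5 largest negative log2 changes with adjusted p below 0.05, a mean of at least 10 FPKM, no overlap between the replicates of the groups (for differences of responses no such requirement), a symbol and no organelle origin; and per list up to 2 rising and 2 falling members of smallest p. The text names fewer, in that order. Small nuclear RNA genes and a microRNA gene below 300 nt were skipped, since FPKM is unreliable at that length. With 3 against 3 libraries, 10% of genes without any difference have groups that do not overlap.

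Alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, organelle-encoded genes removed before scaling, a test against a fold of 1.5, a fit of only the groups compared, each library left out in turn, the replicate number as a block, and fry in place of camera. After the data had been seen, removal of the trend on transcript length and GC content (splines of 6 and 4 degrees of freedom, genes of at least 300 nt) was added. Splits of the libraries into other groups served to weigh chance. The analysis was tested on simulated data with known changes: for NaCl in Col-0 total RNA it recovered 29.9%, 86.6% and 95.5% of 1.2-fold, 1.5-fold and 2-fold changes, and for the difference in association 2.99%, 32.8% and 80.3%, with 3 to 13 false calls among 20964 genes. Only 67, 67 and 66 genes were changed at these folds per comparison, with normal noise independent between genes. The real comparisons called many more genes, up to 13763. Neither the recovery nor the number of false calls therefore describes the lists reported here. Raw reads were not used here.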

Results

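RNA was sequenced from 5-day-old Arabidopsis seedlings of the wild type Col-0 and of the mutant dcp5-1. DCP5 encodes a cytoplasmic protein of the mRNA decapping machinery, which removes the 5' cap of messengers and gathers in processing bodies. Seedlings rested for 30 min in liquid medium and were then placed in medium with 150 mM NaCl for 0 min (T0) or 15 min (T15). From each lysate, total RNA and the RNA of the pooled polysome fractions of a 10 to 50% sucrose gradient were taken. The 2 genotypes, 2 times and 2 RNA fractions made 8 groups of 3 libraries each, 24 in all. No group spent 15 min in medium without NaCl. Changes from T0 to T15, called NaCl changes below, therefore cannot be told apart from effects of transfer, handling or elapsed time. The spacing of low values implied between 12640000 and 16460000 fragments per library, and between 19026 and 19579 genes reached 1 FPKM in each. The p-values and standard errors below rest on the spread between the 3 samples per group, pooled over the 8 groups. Since the labels do not say that these samples came from separate cultures, that spread may be technical. It was small: among genes with high counts, the median coefficient of variation beyond counting error ran from 0.72% (dcp5-1 polysomal RNA at T0) to 6.37% (Col-0 total RNA at T0). The low p-values and large counts of genes below rest on this small spread.

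The deposited columns name no fraction, and those marked IP were read as polysomal RNA. If that reading is wrong, the names of the fractions swap and the sign of every value of polysome association reverses, while changes within each set of columns do not depend on it. In the columns read as polysomal, the median of 66 chloroplast-encoded genes in Col-0 at T0 lay at -0.76 on the log2 scale relative to total RNA, against -0.01 for 19547 protein-coding genes. For 9 mitochondrion-encoded genes the median was -0.40 there, but 0.03 in Col-0 at T15, and 0 and 0.14 in dcp5-1 at T0 and T15. The first principal component held 37.5% of the variance and parted the fractions, from -65.9 to -12.7 for total RNA and from 30.0 to 49.4 for polysomal RNA. Polysome association is used here for the log2 level in polysomal RNA minus that in total RNA. FPKM values are relative within a library and any scaling between libraries is not known, so the amount of RNA on polysomes as a whole could not be measured. A gene that shares reads with close copies, such as the RBCS, LHCB1, SAUR or EF1A families, or with an overlapping or antisense gene, is uncertain at the level of the single copy.

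DCP5 (AT1G26110; chromosome 1, 9024341 to 9027955 in the TAIR10.1 annotation) was lower in every dcp5-1 library than in any Col-0 library of the same time and fraction. At T0, total RNA held 12.99, 12.96 and 13.16 FPKM in dcp5-1 and 48.5, 51.7 and 52.1 FPKM in Col-0, and polysomal RNA held 20.4, 21.4 and 20.1 FPKM against 92.3, 91.8 and 90.7 FPKM. At T15, total RNA held 16.7, 16.8 and 17.0 FPKM against 77.1, 76.8 and 77.2 FPKM, and polysomal RNA held 21.5, 19.7 and 20.6 FPKM against 83.0, 90.8 and 85.8 FPKM. The mutant mean was 25.7% and 22.5% of the Col-0 mean at T0 in total and polysomal RNA, and 21.9% and 23.8% at T15. With organelle-encoded genes removed before scaling, the T0 shares were 30.0% and 25.2%. In Col-0, DCP5 rose from T0 to T15 in total RNA by 0.59 ± 0.04 on the log2 scale (SE, 3 T15 against 3 T0 libraries, limma, adjusted p = 3.9e-11) and its polysome association fell by 0.68 ± 0.06 (adjusted p = 7.8e-09). With the trend on transcript length and GC content removed, these values were 0.36 and -0.45. The change of the remaining DCP5 transcript in dcp5-1 total RNA was 0.35 ± 0.04 (adjusted p = 3.3e-07), and 0.09 with that trend removed (adjusted p = 0.0582).

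**Figure D1:**
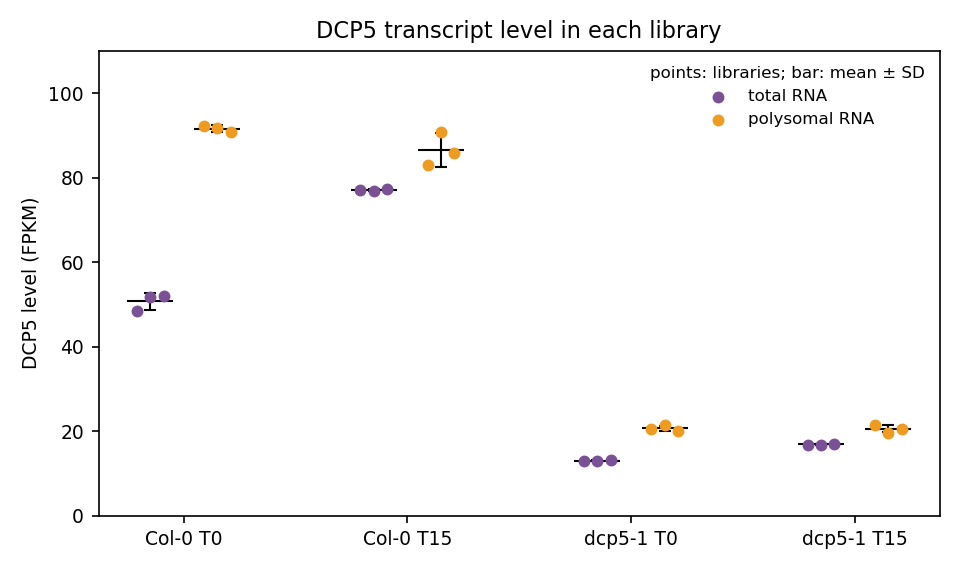
DCP5 level in FPKM (vertical axis) in each of the 24 libraries by genotype, time and fraction, with points for libraries and bars for the group mean ± SD of 3 libraries. The dcp5-1 libraries lay between 12.96 and 21.5 FPKM and the Col-0 libraries between 48.5 and 92.3 FPKM.

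In Col-0 total RNA, CIB1, ARGOS and LTI78 rose and TPX2, EXO and AGP13 fell within 15 min of NaCl. This comparison asks which messengers change in abundance under hypertonic stress in the wild type. CIB1 (AT4G34530), which encodes a transcription factor that binds a blue-light receptor, rose by 3.65 ± 0.23 on the log2 scale (SE, 3 T15 against 3 T0 libraries), from 1.12 ± 0.061 to 25.5 ± 0.37 FPKM (SD). The organ-size gene ARGOS (AT3G59900) rose by 2.42 ± 0.11 and LTI78 (AT5G52310, also RD29A), a marker of osmotic and cold stress, by 2.24 ± 0.08, from 12.0 ± 1.8 to 60.1 ± 2.9 FPKM. TPX2 (AT1G65970), a peroxiredoxin gene, fell by 4.30 ± 0.11, from 544 ± 97 to 26.5 ± 2.7 FPKM. EXO (AT4G08950), linked to brassinosteroid-driven cell expansion, fell by 3.41 ± 0.06, from 763 ± 41 to 70.7 ± 1.1 FPKM, and the arabinogalactan peptide gene AGP13 (AT4G26320) fell by 3.35 ± 0.10. Adjusted p for these 6 genes was at most 6.3e-11 (limma). In all, 6963 genes rose and 6800 fell among 20964 tested, with 241 rising and 1627 falling at least 2-fold. Genes that rose made up 50.6% of those that changed, and 69.8% with organelle-encoded genes removed before scaling, which moved the median of all genes by 0.22.

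Of 35 rapid stress-inducible regulators, 25 fell, 5 rose and 5 did not pass the test, the same counts when adjusted over the list alone. With organelle-encoded genes removed before scaling, 22 fell and 10 rose. The xyloglucan endotransglucosylase gene TCH4 (AT5G57560), induced by touch, fell by 2.91 ± 0.05 and the jasmonate repressor gene JAZ7 (AT2G34600) fell by 3.08 ± 0.07, whereas CBF1 (AT4G25490), a cold-response regulator, rose by 1.54 ± 0.13 (adjusted p of at most 4.1e-10). As a group the list moved down relative to the other genes (camera, adjusted p = 1.8e-06 and adjusted p = 0.106 with an estimated correlation). Among 26 cytosolic ribosomal protein genes 21 fell and 1 rose, likewise over the list alone (camera adjusted p = 5.4e-07 and adjusted p = 0.434 with an estimated correlation). RPL28A (AT2G19730) fell by 1.67 ± 0.08 and RPS10B (AT5G41520) fell by 0.99 ± 0.05. With the length and GC trend removed, they fell by 1.00 and by 0.48 and 18 of the list fell. Of 17 aquaporin genes, which encode water channels, 16 fell and none rose, also over the list alone, with TIP2;2 (AT4G17340) and PIP2A (AT3G53420) at -1.23 ± 0.08 and -0.91 ± 0.08 (camera adjusted p = 8.1e-05 and adjusted p = 0.434 with an estimated correlation). Among 17 genes of mRNA decapping and decay 12 rose and 4 fell, also over the list alone (camera adjusted p = 0.0399 and adjusted p = 0.106 with an estimated correlation). This call ended with organelle-encoded genes removed (adjusted p = 0.164) and with the length and GC trend removed (adjusted p = 0.36). The exonuclease gene SOV (AT1G77680) and the decapping scaffold gene VCS (AT3G13300) rose by 0.89 ± 0.05 and 0.86 ± 0.06, or 0.45 and 0.44 with the trend removed. The deadenylase genes CAF1a (AT3G44260) and CAF1b (AT5G22250) fell by 2.14 ± 0.07 and by 2.12 ± 0.08.

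The other lists gave no group call in Col-0 total RNA. Of 23 ABA and osmotic stress genes 8 rose, among them LTI78 and the drought regulator DREB2A (AT5G05410; 1.78 ± 0.08), and 10 fell, among them the phosphatase gene HAI1 (AT5G59220; -1.93 ± 0.16), or 9 and 10 adjusted over the list alone. That list's median was -0.08 and its mean 0.12 (0.16 for the median with organelle-encoded genes removed). Rising and falling members numbered 3 and 0 of 8 for sodium transport and osmosensing, 7 and 6 of 15 for stress granule RNA-binding proteins (median -0.10, mean 0.06, and a median of 0.17 with organelle-encoded genes removed), 1 and 5 of 8 for seed storage, and 3 and 6 of 15 for translation factors. They numbered 7 and 11 of 24 for nuclear photosynthesis genes, 3 and 6 of 11 for root-expressed genes, 2 and 7 of 12 for heat shock and unfolded protein response, and 6 and 8 of 17 for auxin response. Of 66 chloroplast-encoded genes 3 rose and 20 fell, and of 9 mitochondrion-encoded genes none rose and 5 fell. Adjusted over the list alone, 7 stress granule genes fell, 12 photosynthesis genes fell, 8 heat shock genes fell, 7 auxin genes rose, 13 chloroplast-encoded genes fell, and the remaining counts were equal. With organelle-encoded genes removed before scaling, rising and falling members numbered 12 and 5 for ABA, 7 and 0 for sodium transport, 10 and 2 for stress granules, 2 and 4 for seed storage and 8 and 3 for translation factors. They numbered 12 and 9 for photosynthesis, 4 and 4 for root-expressed genes, 3 and 6 for heat shock and 8 and 5 for auxin. With the length and GC trend removed, the numbers in the same order were 12 and 8, 1 and 2, 5 and 7, 2 and 1, 2 and 7, 9 and 8, 3 and 6, 3 and 7, and 11 and 4. The balance of rising and falling members thus turned under at least 1 of these settings for some lists and not for heat shock genes. Camera adjusted p over these lists ran from 0.26 to 0.76.

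**Figure D2:**
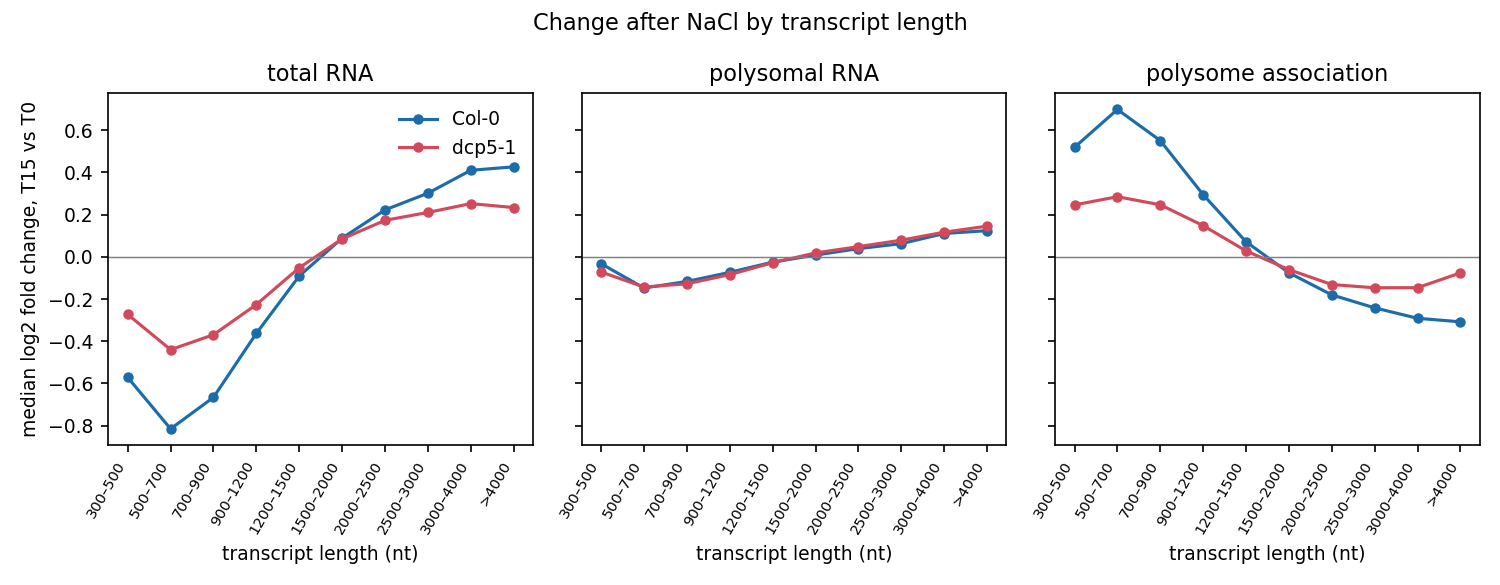
Median log2 change at T15 against T0 (vertical axis) of nuclear protein-coding genes in bins of transcript length in nt (horizontal axis), in total RNA, polysomal RNA and polysome association, with 1 line per genotype. In Col-0 total RNA the median ran from -0.82 for 703 genes of 500 to 700 nt to 0.43 for 601 genes over 4000 nt.

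The change in total RNA went with transcript length. Across 19442 nuclear protein-coding genes of at least 300 nt, which are not independent replicates, its rank correlation with length was 0.60 in Col-0 total RNA, 0.25 in polysomal RNA and -0.60 for polysome association. In dcp5-1 the values were 0.50, 0.30 and -0.43. Length and GC content together accounted for 36.3% of the variance of the change in Col-0 total RNA and for 24% in dcp5-1. Some comparisons between the genotypes went with length too. The rank correlation for the difference in response was -0.40 in total RNA, 0.04 in polysomal RNA and 0.44 for association. For dcp5-1 against Col-0 it was -0.39, -0.05 and 0.50 at T15, against -0.04, -0.09 and -0.07 at T0.

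Polysomal RNA of Col-0 held fewer changed genes than total RNA, and the comparison asks which messengers on polysomes change under NaCl. ARGOS rose by 2.13 ± 0.11 (SE, 3 T15 against 3 T0 libraries), its homologue ARL (AT2G44080) by 1.81 ± 0.07 and LTI78 by 1.80 ± 0.08, from 12.4 ± 0.79 to 45.9 ± 2.7 FPKM. EXO fell by 2.92 ± 0.06, from 802 ± 18 to 105 ± 9.7 FPKM, JAZ7 fell by 2.84 ± 0.07 and TCH4 fell by 2.83 ± 0.05. Adjusted p for these 6 genes was at most 5.3e-12 (limma). In total 3275 genes rose and 3583 fell, with 95 and 181 of them changing at least 2-fold. The rapid regulators moved down (23 fell, 7 rose, likewise over the list alone, camera adjusted p = 6.0e-09), as did the heat shock list, in which 8 of 12 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 7.8e-04). The chaperone genes HSP70 (AT3G12580) and HSP90.1 (AT5G52640) fell by 0.96 ± 0.09 and by 0.64 ± 0.08. Of 11 root-expressed genes 7 fell and 1 rose, likewise over the list alone, with the root-hair expansin gene EXPA18 (AT1G62980) at -0.98 ± 0.13 (camera adjusted p = 0.0029). These 3 calls held with an estimated correlation (adjusted p = 0.016 for each). Ribosomal protein genes (19 fell, none rose, 20 fell over the list alone, camera adjusted p = 4.3e-07) and aquaporin genes (11 fell, none rose, 12 over the list alone, camera adjusted p = 8.1e-05) lost the call there (adjusted p = 0.38 with an estimated correlation for both). RPL23AA (AT2G39460) and TIP2;2 were examples at -0.36 ± 0.05 and -0.85 ± 0.08, and CAF1a and CAF1b fell by 1.67 ± 0.07 and by 1.71 ± 0.08.

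The association of messengers with polysomes in Col-0 moved in both directions, which bears on whether NaCl alters loading beyond abundance. TPX2 rose by 3.62 ± 0.15 in association (SE, 12 libraries, adjusted p = 1.0e-12 by limma), since its polysomal level was 597 ± 2.1 FPKM at T0 and 374 ± 36 FPKM at T15 while total RNA fell as above. AGP13 rose by 2.83 ± 0.14. The myrosinase gene TGG2 (AT5G25980), of glucosinolate defence, fell by 1.88 ± 0.08: its total RNA level went from 19.1 ± 0.81 to 81.7 ± 2.6 FPKM and its polysomal level from 73.9 ± 2.3 to 82.7 ± 3.0 FPKM. The lipase-like gene GLL22 (AT1G54000) fell by 1.63 ± 0.09. Association rose for 4786 genes and fell for 4503, at least 2-fold for 945 and 63. Genes that rose made up 51.5% of those that changed, and 26.9% with organelle-encoded genes removed, which moved the median of all genes by -0.20. Ribosomal protein genes rose in association (18 of 26, 3 fell, likewise over the list alone, camera adjusted p = 1.5e-04 and adjusted p = 0.675 with an estimated correlation), with RPL28A (AT2G19730) at 1.38 ± 0.12, or 0.83 with the length and GC trend removed. Of this list 13 rose and 6 fell with organelle-encoded genes removed, and 12 rose and 4 fell with the trend removed. Of the rapid regulators 18 rose and 1 fell (19 and 2 over the list alone, camera adjusted p = 0.012 and adjusted p = 0.466 with an estimated correlation), a call that ended with organelle-encoded genes removed (8 rose, 7 fell, adjusted p = 0.126) or the trend removed (11 rose, 6 fell, adjusted p = 0.26).

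In dcp5-1 total RNA, which shows how the mutant responds, many of the same named genes changed. CIB1 rose by 2.94 ± 0.23 (SE, 3 T15 against 3 T0 libraries), from 4.94 ± 1.3 to 44.0 ± 2.6 FPKM, TGG2 by 2.77 ± 0.05 and DREB2A by 2.28 ± 0.08. TPX2 fell by 3.28 ± 0.11, from 331 ± 26 to 33.3 ± 5.5 FPKM, JAZ7 fell by 3.07 ± 0.07 and EXO fell by 2.60 ± 0.06, from 421 ± 28 to 68.5 ± 3.4 FPKM. Adjusted p for these 6 genes was at most 2.3e-09 (limma). In total 6070 genes rose and 5614 fell, at least 2-fold for 236 and 539. Nuclear photosynthesis genes rose (16 of 24, 3 fell, likewise over the list alone, camera adjusted p = 0.0051 and adjusted p = 0.512 with an estimated correlation), among them the Rubisco activase gene RCA (AT2G39730; 1.90 ± 0.06) and the antenna gene LHCB6 (AT1G15820; 0.89 ± 0.06). Heat shock genes fell (9 of 12, 2 rose, 9 and 3 over the list alone, camera adjusted p = 0.038 and adjusted p = 0.155 with an estimated correlation), with the small heat shock gene HSP17.6A (AT5G12030) at -1.72 ± 0.11 and HSP70 at -1.31 ± 0.09. Of the rapid regulators 20 fell and 9 rose (21 and 9 over the list alone, camera adjusted p = 0.0014 and adjusted p = 0.233 with an estimated correlation), with CBF1 and the defence regulator WRKY33 (AT2G38470) at 2.42 ± 0.13 and 1.15 ± 0.06. Of the ribosomal protein genes 20 fell and 4 rose, likewise over the list alone (camera adjusted p = 1.0e-04 and adjusted p = 0.512 with an estimated correlation).

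Lists with weaker calls in dcp5-1 total RNA were decapping and decay (12 rose, 4 fell), ABA and osmotic stress (11 rose, 6 fell), aquaporins (1 rose, 8 fell) and chloroplast-encoded genes (none rose, 14 fell, 7 over the list alone). Their camera adjusted p was between 0.0382 and 0.0407, and each lost the call with an estimated correlation (adjusted p = 0.155, 0.317, 0.53 and 0.512 in that order). With organelle-encoded genes removed, the decapping and ABA lists lost it too (adjusted p = 0.0902 and 0.0534), and with the length and GC trend removed the decapping list did (adjusted p = 0.474). Counts over the list alone were equal except for the chloroplast genes.

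Polysomal RNA of dcp5-1 under NaCl gained the cold- and jasmonate-linked transcripts COR15A and LOX2, a comparison of the messengers on polysomes within the mutant. CIB1 rose by 2.28 ± 0.23 (SE, 3 T15 against 3 T0 libraries), the chloroplast cold-protection gene COR15A (AT2G42540) by 1.80 ± 0.13 and the jasmonate lipoxygenase gene LOX2 (AT3G45140) by 1.72 ± 0.05, from 17.7 ± 0.91 to 60.7 ± 0.90 FPKM. JAZ7 fell by 2.93 ± 0.07 and EXO fell by 2.34 ± 0.06 (adjusted p of at most 3.7e-07 for these 5 genes, limma). In total 3609 genes rose and 3259 fell, at least 2-fold for 91 and 108. Genes that rose made up 52.5% of those that changed, and 30.8% with organelle-encoded genes removed. Heat shock genes fell (9 of 12, none rose, likewise over the list alone), with the heat stress factor gene HSFA2 (AT2G26150) at -1.37 ± 0.11 and HSP17.6A at -1.30 ± 0.11 (camera adjusted p = 1.0e-06 and adjusted p = 6.5e-04 with an estimated correlation). Photosynthesis genes rose (18 of 24, none fell, 19 and 1 over the list alone, camera adjusted p = 4.0e-07 and adjusted p = 0.394 with an estimated correlation), with the antenna gene CAB3 (AT1G29910) at 0.79 ± 0.08. The rapid regulators fell (19, 9 rose, likewise over the list alone, camera adjusted p = 4.5e-04 and adjusted p = 0.208 with an estimated correlation), although CBF2 (AT4G25470), another cold-response regulator, rose by 1.72 ± 0.09. Ribosomal protein genes fell (11, none rose, 12 over the list alone, camera adjusted p = 8.7e-04 and adjusted p = 0.56 with an estimated correlation), or 20 with organelle-encoded genes removed. The seed list (4 rose, none fell, likewise over the list alone) and the ABA list (10 rose, 5 fell, 10 and 8 over the list alone) had camera adjusted p = 0.028 and 0.039, and adjusted p = 0.25 and 0.27 with an estimated correlation. The ABA list's median of 0.04 became -0.04 with organelle-encoded genes removed, where 9 rose and 10 fell.

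Polysome association in dcp5-1 changed for fewer genes, with TPX2 again at the top (2.79 ± 0.15, SE, 12 libraries; adjusted p = 6.0e-11, limma), followed by AGP13 (2.04 ± 0.14). TGG2 fell by 2.23 ± 0.08 and ABA1 (AT5G67030), of ABA synthesis, fell by 1.42 ± 0.06. Association rose for 2575 genes and fell for 2931, at least 2-fold for 174 and 41. Genes that rose made up 46.8%, and 27.9% with organelle-encoded genes removed, which moved the median by -0.11. Ribosomal protein genes rose (12 of 26, 3 fell, 13 and 4 over the list alone, camera adjusted p = 0.0074 and adjusted p = 0.68 with an estimated correlation), with RPL28A (AT2G19730) at 0.79 ± 0.12, or 0.52 with the length and GC trend removed, where the list lost its call (adjusted p = 0.183). Sodium transport (3 fell, none rose, 4 fell over the list alone), aquaporins (2 rose, likewise over the list alone) and chloroplast-encoded genes (5 rose, none over the list alone) had camera adjusted p = 0.048 and adjusted p = 0.26, 0.80 and 0.68 with an estimated correlation. The sodium and aquaporin calls ended with organelle-encoded genes removed (adjusted p = 0.0539 and 0.112) and with the trend removed (adjusted p = 0.248 and 0.114).

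Before NaCl, heat shock genes were higher in dcp5-1 than in Col-0, in the comparison that gives the mutant's starting state. In total RNA, ESM1 (AT3G14210), which directs glucosinolate breakdown, was higher in dcp5-1 by 4.09 ± 0.07 (SE, 3 dcp5-1 against 3 Col-0 libraries), at 99.9 ± 3.7 against 4.95 ± 0.74 FPKM. The light-stress gene ELIP1 (AT3G22840) was higher by 3.02 ± 0.08, at 246 ± 13 against 29.7 ± 4.6 FPKM, and HSP90.1 by 2.88 ± 0.08, at 34.7 ± 2.5 against 3.87 ± 0.46 FPKM. The aldolase gene FBA5 (AT4G26530) and the kinase gene CIPK20 (AT5G45820) were lower, at -2.94 ± 0.09 and -2.41 ± 0.08. Adjusted p for these 5 genes was at most 9.8e-16 (limma). In total 4087 genes were higher and 5988 lower, at least 2-fold for 212 and 371. Higher genes made up 40.6%, and 73.1% with organelle-encoded genes removed, which moved the median by 0.18. Heat shock genes were higher (9 of 12, 1 lower, likewise over the list alone, camera adjusted p = 1.1e-07 and adjusted p = 3.4e-04 with an estimated correlation). The rapid regulators were lower (24 of 35, 2 higher, likewise over the list alone, camera adjusted p = 5.0e-09 and adjusted p = 0.019 with an estimated correlation), with WRKY33 and the zinc-finger gene SZF1 (AT3G55980) at -1.41 ± 0.06 and -1.33 ± 0.06. Of these regulators 21 were lower and 7 higher with organelle-encoded genes removed. Of 24 nuclear photosynthesis genes 23 were lower and none higher, likewise over the list alone, among them the antenna genes LHCA1 (AT3G54890; -0.90 ± 0.05) and CAB3 (-1.34 ± 0.08) (camera adjusted p = 2.4e-13 and adjusted p = 0.143 with an estimated correlation).

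Further lists were called lower in dcp5-1 total RNA at T0, and for the decapping and ABA lists this depended on the scaling. Of 17 decapping and decay genes, DCP5 among them, 11 were lower and 1 higher (11 and 2 over the list alone, camera adjusted p = 0.012 and adjusted p = 0.035 with an estimated correlation), a call that ended with organelle-encoded genes removed, where 5 were lower and 4 higher (adjusted p = 0.0547). The seed list (5 of 8 lower, none higher, 5 and 1 over the list alone, camera adjusted p = 0.0060 and adjusted p = 0.111 with an estimated correlation) included the oleosin gene OLEO2 (AT5G40420), of seed oil bodies, at -3.28 ± 0.11. The auxin list had 13 lower and 4 higher of 17, likewise over the list alone (camera adjusted p = 0.016 and adjusted p = 0.117 with an estimated correlation). The ABA list had 14 lower and 2 higher (14 and 3 over the list alone, camera adjusted p = 0.026 and adjusted p = 0.17 with an estimated correlation, and 8 lower, 8 higher and adjusted p = 0.0511 with organelle-encoded genes removed), and the chloroplast-encoded list 25 lower and 1 higher (24 and 1 over the list alone, camera adjusted p = 0.036 and adjusted p = 0.50 with an estimated correlation).

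In polysomal RNA at T0, which compares the mutant's messengers on polysomes, ESM1 stood at 342 ± 7.8 FPKM against 8.94 ± 0.55 FPKM in Col-0, higher by 5.11 ± 0.07 (SE, 3 dcp5-1 against 3 Col-0 libraries), and ELIP1 was higher by 3.44 ± 0.08. The cutinase gene CDEF1 (AT4G30140) was lower at -3.01 ± 0.06, with 4.79 ± 0.15 against 45.5 ± 1.4 FPKM, and FBA5 at -2.54 ± 0.09 (adjusted p of at most 2.1e-15 for the 4 genes, limma). In total 4585 genes were higher and 5029 lower, at least 2-fold for 270 and 232. Higher genes made up 47.7%, and 74.5% with organelle-encoded genes removed, which moved the median by 0.13. Heat shock genes were higher (10 of 12, 1 lower, likewise over the list alone, camera adjusted p = 2.6e-08 and adjusted p = 1.8e-04 with an estimated correlation), with HSP90.1 at 2.77 ± 0.08. The rapid regulators were lower (20, 4 higher, 21 and 4 over the list alone, camera adjusted p = 2.3e-07 and adjusted p = 0.045 with an estimated correlation), with TCH4 at -1.03 ± 0.05. Of these regulators 20 were lower and 9 higher with organelle-encoded genes removed. Photosynthesis genes were lower (23 of 24, none higher, likewise over the list alone, camera adjusted p = 7.8e-15 and adjusted p = 0.173 with an estimated correlation), with CAB3 at -1.57 ± 0.08. The seed list was lower (5 of 8, likewise over the list alone, camera adjusted p = 0.0023 and adjusted p = 0.098 with an estimated correlation), and ribosomal protein genes were higher (9 of 26, none lower, likewise over the list alone, camera adjusted p = 0.011 and adjusted p = 0.81 with an estimated correlation), with RPL3B (AT1G61580) at 1.21 ± 0.06. With organelle-encoded genes removed, 21 ribosomal protein genes were higher.

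Polysome association at T0 differed between the genotypes for 2280 genes, 10.9% of those tested, or 1375 when only the groups compared were fitted. The comparison asks whether the mutant loads messengers differently before stress. The glucosinolate sulfotransferase gene SOT18 (AT1G74090) was higher in association by 1.85 ± 0.14 (SE, 12 libraries) and ESM1 by 1.02 ± 0.10, while CDEF1 and the xylem protease gene XCP1 (AT4G35350) were lower at -0.91 ± 0.08 and -0.82 ± 0.10 (adjusted p of at most 1.2e-05, limma). SOT18 stood at 12.2 ± 0.80 FPKM in total and 26.9 ± 2.2 FPKM in polysomal RNA of dcp5-1, and at 14.9 ± 2.1 and 8.33 ± 0.56 FPKM in Col-0. In total 1621 genes were higher and 659 lower, at least 2-fold for 23 and 6. Higher genes made up 71.1%, and 57.0% with organelle-encoded genes removed or 54.9% with the length and GC trend removed. Translation factors were higher (5 of 15, none lower, likewise over the list alone, camera adjusted p = 0.024 and adjusted p = 0.628 with an estimated correlation), with EIF4A1 (AT3G13920) at 0.58 ± 0.10. Of these factors 3 were higher and 1 lower with organelle-encoded genes removed. The rapid regulators were too (6, none lower, 7 over the list alone, camera adjusted p = 0.024 and adjusted p = 0.63 with an estimated correlation, and 3 higher and adjusted p = 0.0515 with organelle-encoded genes removed).

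After 15 min of NaCl, ESM1 and OEP6 were higher and CDEF1 and CIPK20 lower in total RNA of dcp5-1 than of Col-0, in the comparison of the stressed genotypes. ESM1 was higher by 3.56 ± 0.07 (SE, 3 dcp5-1 against 3 Col-0 libraries) and the chloroplast envelope gene OEP6 (AT3G63160) by 3.22 ± 0.11, at 627 ± 24 against 66.2 ± 2.0 FPKM. CDEF1 was lower at -2.62 ± 0.06 and CIPK20 at -2.25 ± 0.08 (adjusted p of at most 3.4e-15 for the 4 genes, limma). In total 5024 genes were higher and 5466 lower, at least 2-fold for 381 and 166. Ribosomal protein genes were higher (23 of 26, none lower, 24 over the list alone, camera adjusted p = 1.9e-08 and adjusted p = 0.363 with an estimated correlation), with RPL3B at 0.83 ± 0.06. Heat shock genes were higher (10 of 12, none lower, likewise over the list alone, camera adjusted p = 1.1e-04 and adjusted p = 0.0048 with an estimated correlation), with HSP90.1 at 2.25 ± 0.08. Decapping and decay genes were lower (11 of 17, 2 higher, likewise over the list alone, camera adjusted p = 0.0029 and adjusted p = 0.017 with an estimated correlation, and 7 lower, 1 higher and adjusted p = 0.0744 with the length and GC trend removed). Photosynthesis genes (18 lower, 2 higher, 19 and 2 over the list alone), rapid regulators (22 lower, 7 higher, 22 and 9 over the list alone), auxin genes (9 lower, 2 higher, likewise over the list alone) and chloroplast-encoded genes (25 lower, none higher, 24 over the list alone) were lower as groups. Their camera adjusted p was 7.5e-04, 0.0064, 0.0064 and 0.0042, and adjusted p = 0.54, 0.36, 0.13 and 0.36 with an estimated correlation.

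In polysomal RNA at T15 the auxin list was lower in dcp5-1, in the comparison of messengers on polysomes of stressed seedlings. ESM1 was higher by 4.21 ± 0.07 (SE, 3 dcp5-1 against 3 Col-0 libraries) and OEP6 by 3.31 ± 0.11, while CDEF1 and the myo-inositol oxygenase gene MIOX2 (AT2G19800) were lower at -3.04 ± 0.06 and -2.16 ± 0.05 (adjusted p of at most 1.2e-15, limma). In total 4683 genes were higher and 4688 lower, at least 2-fold for 302 and 173. Of the auxin genes 13 of 17 were lower and 2 higher, likewise over the list alone (camera adjusted p = 8.8e-05 and adjusted p = 0.023 with an estimated correlation), with the auxin-inducible regulator genes HAT2 (AT5G47370) and IAA1 (AT4G14560) at -1.10 ± 0.06 and -1.09 ± 0.07. Heat shock genes were higher (8, 2 lower, 9 and 2 over the list alone, camera adjusted p = 1.2e-05 and adjusted p = 0.0018 with an estimated correlation), with HSP90.1 at 2.80 ± 0.08. Photosynthesis genes were lower (22, 1 higher, likewise over the list alone, camera adjusted p = 1.9e-09 and adjusted p = 0.316 with an estimated correlation), and so were the rapid regulators (19, 5 higher, 21 and 5 over the list alone, camera adjusted p = 0.0040 and adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes (18 higher, none lower, 19 over the list alone, camera adjusted p = 2.3e-05) and translation factors (5 higher, none lower, likewise over the list alone, camera adjusted p = 0.034) lost the call elsewhere (adjusted p = 0.49 with an estimated correlation for both). Translation factors that were higher numbered 10 with organelle-encoded genes removed.

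Polysome association at T15 was higher in dcp5-1 for SOT18 (1.80 ± 0.14, SE, 12 libraries) and LOX2 (0.90 ± 0.07) and lower for TPX2 (-1.22 ± 0.15) and the autophagy gene ATG8E (AT2G45170; -0.98 ± 0.10) (adjusted p of at most 3.2e-05, limma). The comparison asks whether loading under stress differs between the genotypes. In total 1568 genes were higher and 1114 lower, at least 2-fold for 16 and 24, and 594 were higher and 645 lower with the length and GC trend removed. Higher genes made up 58.5%, and 69.1% with organelle-encoded genes removed or 47.9% with the length and GC trend removed. Decapping and decay genes were higher (7 of 17, none lower, likewise over the list alone, camera adjusted p = 3.2e-04 and adjusted p = 0.0066 with an estimated correlation), with the helicase gene UPF1 (LBA1, AT5G47010) at 0.52 ± 0.07 and VCS at 0.50 ± 0.08. With the length and GC trend removed, these genes stood at 0.22 and 0.21 (adjusted p = 0.0721 and 0.142) and the list lost its call with 1 member higher (adjusted p = 0.123). Photosynthesis genes were lower (8 of 24, none higher, 9 over the list alone, camera adjusted p = 6.3e-05 and adjusted p = 0.673 with an estimated correlation), with CAB3 at -0.75 ± 0.12. Ribosomal protein genes were lower (4, 1 higher, 5 and 1 over the list alone, camera adjusted p = 0.046 and adjusted p = 0.75 with an estimated correlation; adjusted p = 0.294 with the trend removed).

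**Figure D3:**
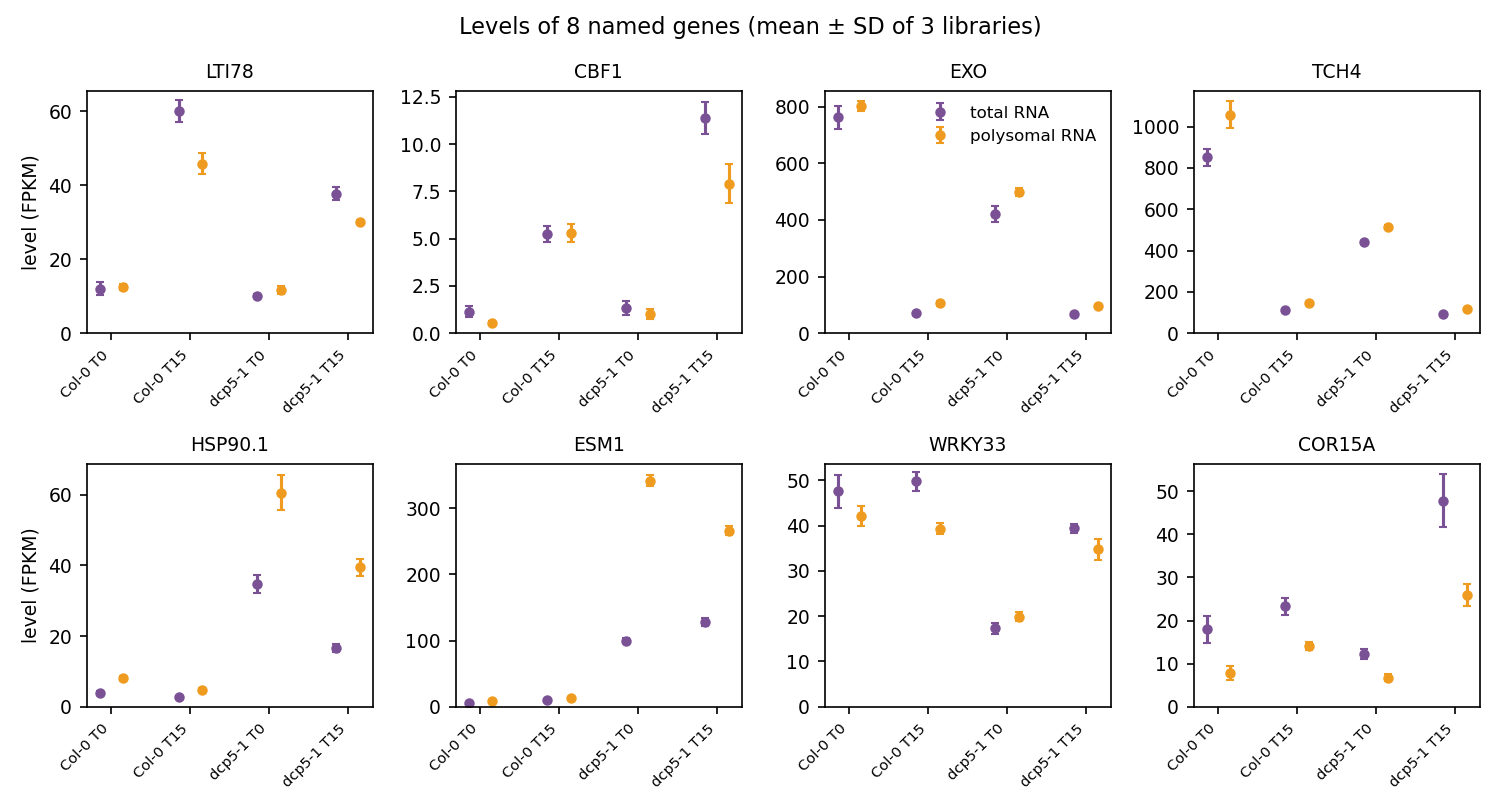
Level in FPKM (vertical axis) of 8 named genes by time of NaCl in total and polysomal RNA of both genotypes, with points for the mean and bars for the SD of 3 libraries. EXO went from 763 to 70.7 FPKM in Col-0 total RNA and from 421 to 68.5 FPKM in dcp5-1, and ESM1 stood at 99.9 FPKM against 4.95 FPKM before NaCl.

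Whether NaCl acted differently on the genotypes was tested as a difference of the 2 changes. In total RNA, ECS1 (AT1G31580), a cell wall protein gene, responded more positively in dcp5-1 by 1.98 ± 0.13 (SE, 12 libraries): it went from 362 ± 9.5 to 596 ± 14 FPKM in dcp5-1 and from 596 ± 63 to 247 ± 9.8 FPKM in Col-0. The methionine sulfoxide reductase gene MSRB5 (AT4G04830) differed by 1.66 ± 0.11, the cytokinin response factor gene CRF10 (AT1G68550) by -0.83 ± 0.10 and the aminotransferase gene BCAT-2 (AT1G10070) by -0.82 ± 0.12 (adjusted p of at most 3.9e-05 for the 4 genes, limma). DCP5 itself differed by -0.25 ± 0.06 (adjusted p = 0.0038), or -0.48 with organelle-encoded genes removed. The response was more positive in dcp5-1 for 3535 genes and more negative for 1748, by at least 2-fold for 242 and 14. This difference went with transcript length, at a rank correlation of -0.40. Its median was 0.42 for nuclear protein-coding genes of 500 to 700 nt and -0.21 for those over 4000 nt. More positive genes made up 66.9%, and 23.7% with organelle-encoded genes removed, which moved the median by -0.19. WRKY33 (1.08 ± 0.09) and CBF2 (1.3 ± 0.12) were among 19 of 35 rapid regulators with a more positive response, against 3 more negative (24 and 3 over the list alone, camera adjusted p = 1.1e-08 and adjusted p = 0.023 with an estimated correlation). WRKY33 went from 17.3 ± 1.2 to 39.4 ± 0.96 FPKM in dcp5-1 and from 47.6 ± 3.7 to 49.8 ± 2.1 FPKM in Col-0. Root-expressed genes (6 more positive of 11, none more negative, 7 over the list alone) and heat shock genes (6 more negative of 12, 1 more positive, 8 and 1 over the list alone) had camera adjusted p = 0.0036, and adjusted p = 0.023 with an estimated correlation. Of the root-expressed genes 3 were more positive with organelle-encoded genes removed. PYK10 (AT3G09260), of the root ER bodies, differed by 0.73 ± 0.07 and HSP90.1 by -0.63 ± 0.12.

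Several lists had a more positive response in dcp5-1 total RNA but no call with an estimated correlation. Photosynthesis genes (22 of 24, none more negative, 23 over the list alone, camera adjusted p = 1.1e-11 and adjusted p = 0.184 with an estimated correlation) included the antenna gene CAB2 (AT1G29920) at 0.92 ± 0.09. Ribosomal protein genes (17, none more negative, 19 and 1 over the list alone, camera adjusted p = 4.7e-06 and adjusted p = 0.359 with an estimated correlation) and aquaporin genes (10, none more negative, 12 over the list alone, camera adjusted p = 8.2e-05 and adjusted p = 0.36 with an estimated correlation) numbered 8 (2 more negative) and 4 with organelle-encoded genes removed. The seed list (5 of 8, likewise over the list alone, camera adjusted p = 0.0024) and the ABA list (11, 1 more negative, 12 and 2 over the list alone, camera adjusted p = 0.0046) had adjusted p = 0.082 and 0.11 with an estimated correlation. Of the ABA genes 8 were more positive and 5 more negative with organelle-encoded genes removed. Of the translation factors 9 were more positive and none more negative (11 and 1 over the list alone, camera adjusted p = 0.017 and adjusted p = 0.36 with an estimated correlation), which became 2 and 4 with organelle-encoded genes removed. Removal of the length and GC trend left 11 ribosomal protein genes, 4 translation factors, 20 photosynthesis genes and 10 aquaporin genes more positive.

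In polysomal RNA, CYP79F1 and VSP2 were among the genes with a more positive response in dcp5-1. CYP79F1 (AT1G16410), of aliphatic glucosinolate synthesis, responded more positively in dcp5-1 by 1.82 ± 0.09 (SE, 12 libraries), going from 5.99 ± 0.26 to 21.0 ± 1.6 FPKM there and from 9.97 ± 0.54 to 8.73 ± 0.17 FPKM in Col-0. The jasmonate-responsive gene VSP2 (AT5G24770) differed by 1.75 ± 0.07, CIB1 by -1.36 ± 0.32 and MIOX2 by -1.06 ± 0.07 (adjusted p of at most 0.0097, limma). CIB1 lost its call when only the groups compared were fitted (adjusted p = 0.0641) and stood at -2.88 with a pseudocount of 0.1. The response was more positive for 1361 genes and more negative for 932, by at least 2-fold for 61 and 23. More positive genes made up 59.4%, and 29.3% with organelle-encoded genes removed. The rapid regulators (16 more positive, 3 more negative, 19 and 4 over the list alone, camera adjusted p = 2.1e-06), with TCH4 at 0.68 ± 0.07 and WRKY33 at 0.87 ± 0.09, the seed list (4 and none, 5 over the list alone, camera adjusted p = 3.2e-05), root-expressed genes (4 and none, 5 over the list alone, camera adjusted p = 0.0014) and auxin genes (none and 6, 8 over the list alone, camera adjusted p = 6.7e-04) had adjusted p = 0.029 with an estimated correlation. The auxin repressor gene IAA29 (AT4G32280) differed by -1.29 ± 0.20. Photosynthesis genes (7 and none, 10 over the list alone, camera adjusted p = 2.7e-06) and aquaporins (7 and none, 10 over the list alone, camera adjusted p = 2.4e-05) had adjusted p = 0.379 with an estimated correlation, and heat shock genes (none and 4, likewise over the list alone, camera adjusted p = 0.035) adjusted p = 0.067. The ribosomal protein list (1 and none, none over the list alone, camera adjusted p = 0.0497 and adjusted p = 0.70 with an estimated correlation) had a median of 0.09, which became -0.03 with organelle-encoded genes removed (adjusted p = 0.311).

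**Figure D4:**
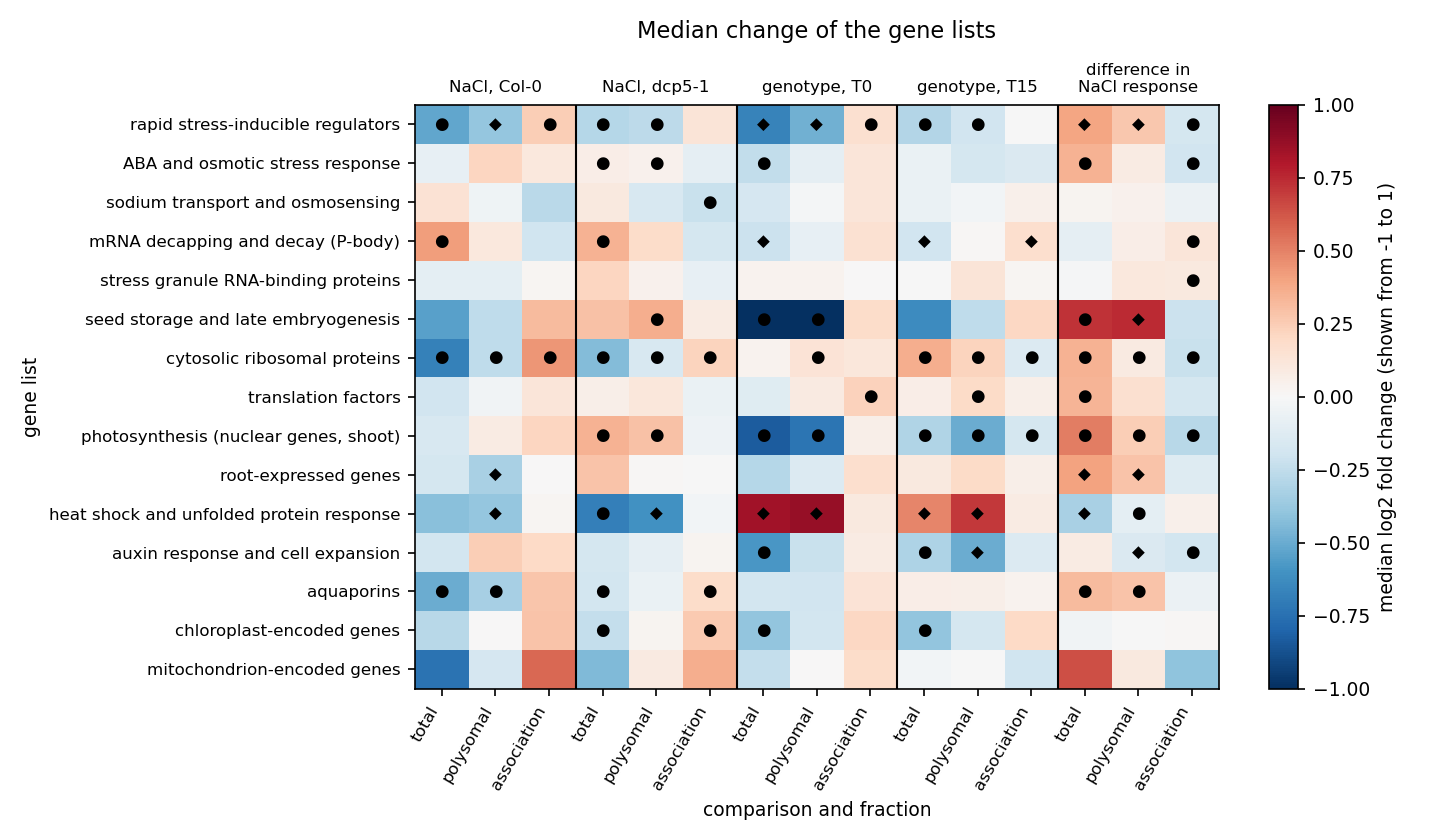
Median log2 change of the 15 gene lists (vertical axis) in the 15 comparisons (horizontal axis), coloured from -1 to 1, with diamonds for group calls that held with an estimated correlation and dots for those with the preset correlation only. Heat shock genes had a median of 0.84 in dcp5-1 total RNA at T0.

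The responses in polysome association differed for the fewest genes of these 3 comparisons. LOX2 responded more positively in dcp5-1 by 0.87 ± 0.10 (SE, 24 libraries), and FHL (AT5G02200), which acts in light signalling through phytochrome A, more negatively at -1.31 ± 0.24 (adjusted p of at most 0.0039, limma). The response was more positive for 409 genes and more negative for 902, by at least 2-fold for 9 and 108. The total of 1311 genes became 627 with the length and GC trend removed and 2103 without Col-0 T0 total RNA library 0. More positive genes made up 31.2%, and 50.6% with organelle-encoded genes removed. Photosynthesis genes (2 of 24 more negative, 4 over the list alone, camera adjusted p = 3.6e-04 and adjusted p = 0.592 with an estimated correlation), with CAB2 at -0.61 ± 0.13, and ribosomal protein genes (2 more negative, likewise over the list alone, camera adjusted p = 0.0042 and adjusted p = 0.69 with an estimated correlation) moved down as groups. The rapid, ABA, decapping, stress granule and auxin lists had camera adjusted p between 0.0464 and 0.0475, and adjusted p of at least 0.375 with an estimated correlation. All of these 5 except the stress granule list lost the call with organelle-encoded genes removed, and all 5 with the length and GC trend removed.

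Genes called in both genotypes mostly changed in the same direction. In total RNA 4806 genes rose and 4663 fell in both, where independent lists of those sizes would share 2016 and 1821, and 97.1% of 9747 genes called in both had the same direction. The shares were 94.5% of 3808 genes in polysomal RNA and 99.2% of 4392 genes for polysome association, and Pearson's r of the changes across genes, which are not independent replicates, was 0.71, 0.46 and 0.54. The NaCl changes of both genotypes also went with transcript length. Their rank correlations were 0.60 in Col-0 and 0.50 in dcp5-1 for total RNA, and -0.60 and -0.43 for association. How much of the overlap this shared trend accounts for was not tested. The genotype difference had the same direction at both times for 90.8% of 6523 genes in total RNA, 96.9% of 6348 in polysomal RNA and 85.7% of 719 for association. The comparisons use separate libraries, so no control is shared.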

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

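The test of the difference between the genotypes' responses was planned, while for the patterns below the tests of DCP5 as a requirement and all tests of the heat shock pattern were chosen only after the result was seen. By the planned test, the response to NaCl differed between dcp5-1 and Col-0 for 5283 genes in total RNA, 2293 in polysomal RNA and 1311 in polysome association. In total RNA the differences were 1.98 for ECS1, 1.66 for MSRB5, -0.83 for CRF10, -0.82 for BCAT-2, 1.08 for WRKY33, 1.3 for CBF2, -0.25 for DCP5, 0.92 for CAB2, 0.73 for PYK10 and -0.63 for HSP90.1. In polysomal RNA they were 1.82 for CYP79F1, 1.75 for VSP2, -1.36 for CIB1, -1.06 for MIOX2, 0.68 for TCH4, 0.87 for WRKY33 and -1.29 for IAA29. For polysome association they were 0.87 for LOX2, -1.31 for FHL and -0.61 for CAB2.

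The NaCl change in Col-0 total RNA followed transcript length, and a length bias that varies from library to library was excluded: the slope of level on length differed between T15 and T0 by 18.183 times the SD between replicates. Abundance rather than length was excluded by a rank correlation of 0.58554 with mean level held fixed, and GC content rather than length by correlations of at least 0.54654 within bins of genes by GC. A process that needs DCP5 cannot be told apart from one that does not: the correlation was 0.49538 in dcp5-1, but the mutant kept 25.7% and 21.9% of the Col-0 DCP5 transcript in total RNA at T0 and T15. A difference in preparation shared by all libraries of a group was not tested and may remain, and messenger decay was not measured.

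Heat shock genes were higher in dcp5-1 before NaCl. Scaling of the libraries was excluded by a list median of 1.0315 in total RNA with organelle-encoded genes removed, and the length and GC trend by a median of 0.93384 with the trend removed. A state of the T0 dishes alone was excluded as the source of the whole difference by a median of 0.48471 at T15 (quartiles 0.22422 and 1.4227). Since the median in total RNA at T0 was 0.84, such a state may still account for part of the difference at T0. A difference in growth or handling between the genotypes, which is confounded with genotype, was not tested.

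At both times and in both fractions, 163 genes differed at least 2-fold in the same direction, 92 higher and 71 lower in dcp5-1. A segment linked to DCP5 from another parent was excluded as a source of many of these genes: with DCP5 itself left out, 1 of these genes (AT1G26450, named after its values were seen) was among 393 tested genes within 1 Mb of DCP5, 0.32809 times the share of all tested genes. For a segment elsewhere in the genome, the fullest 1 Mb window held 5 of them against a median of 6 in 1000 random draws (permutation p of 0.95). Such a segment was not excluded, since one with only a few of these genes would not raise that count above the random draws.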

How the results depend on the processing

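Only the removal of the length and GC trend was chosen after the data had been seen; the other alternatives were fixed before the data were examined, and the planned second count-based tool was not run because the values are FPKM. In the order total RNA, polysomal RNA and association, a test against a fold of 1.5 left 2819, 295 and 921 genes for NaCl in Col-0, 1360, 207 and 174 in dcp5-1, 679, 579 and 1 between the genotypes at T0, 642, 583 and 1 at T15, and 77, 21 and 1 for the difference in response, since that test is stricter. Removing the length and GC trend left 1239 genes for the genotype difference in association at T15 and 627 for the difference in response in association. A fit of only the groups compared gave 1375 genes for association at T0. Leaving out single libraries moved the difference in response in association between 899 (without dcp5-1 T15 total RNA library 2) and 2103 (without Col-0 T0 total RNA library 0). Of the gene set tests 84 were called, 21 with an estimated correlation, 141 with fry directional and 194 with fry mixed. Fry tests a list against no change and camera against the other genes, so these counts are not like for like. Of the 84 calls, 8 ended with a pseudocount of 0.1, 4 without the filter and 5 with median-of-ratios scaling. Of 80 calls, 14 ended with organelle-encoded genes removed and 15 with the trend removed. With organelle-encoded genes removed before scaling, DCP5 in dcp5-1 stood at 29.952% of Col-0 in total RNA and 25.234% in polysomal RNA at T0. Apart from the stricter test, the cause was not tested for these changes. Of 134 named values none reversed under an alternative, 131 kept their call with the trend removed and 33 lost it in the test against a fold of 1.5. Apart from DCP5, these genes were picked by size of change or p in the same data, so this says little about other genes.

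With the column number as replicate block, 522 genes differed in association between the genotypes at T0, 1787 at T15, and 818 for the difference in response, against 11727 genes for NaCl in Col-0 total RNA. The numbers gave no sign of a pairing of the samples. The correlation was taken across genes on what remained of each library once the mean of its group was subtracted. For polysomal and total RNA libraries with the same number it ran from -0.103 to 0.0368, and 1 of 12 correlated best with its own number. That does not show that the samples are unpaired, since the numbers may not mark the lysates.

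For the comparisons within 1 fraction there are 10 splits of the libraries into groups, too few for a share under 0.05. The real grouping alone (1 split) reached its count, with 12502 genes against at most 6 for NaCl in Col-0 total RNA, 5857 against 8 in polysomal RNA, 11772 against 3 and 7089 against 11 in dcp5-1, 7943 against 6 and 9684 against 5 between the genotypes at T0, and 10640 against 3 and 8573 against 6 at T15. For association, 7 of 100 splits had as many genes for NaCl in Col-0 (8151, highest other 9621), 7 in dcp5-1 (6167, highest other 8220), 8 for genotype at T0 (1375, highest other 1977) and 5 at T15 (2679, highest other 4071), shares that by themselves do not exclude chance. The other splits counted there, 6, 6, 7 and 4 in that order, kept or swapped whole the labels of 1 fraction and so carried the real difference, and the 73 splits that mixed the labels of both fractions gave at most 6, 4, 3 and 5 genes. For the difference in response, 1 of 100 splits had as many genes in total RNA (4194, highest other 4072), 3 in polysomal RNA (2453, highest other 2822) and 4 for association (1311, highest other 8179). These shares do not exclude chance. Splits that mix the genotypes also remove the genotype difference present at each time, so they do not show what equal responses would give. Here too the other splits with as many genes kept some of the labels whole, which points to the structure of the samples.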

Other observations

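Before NaCl, short messengers were lower in the columns read as polysomal than in total RNA, in both genotypes. Fewer short messengers on polysomes cannot be told apart here from an excess of them in the T0 total RNA libraries. The median polysome association of nuclear protein-coding genes of 500 to 700 nt was -1.05 in Col-0 and -0.84 in dcp5-1 at T0, and -0.33 and -0.53 at T15. For genes over 4000 nt it was 0.25 and 0.29 at T0, and -0.09 and 0.19 at T15. The median of 116 transcribed pseudogenes was -0.40 in Col-0 and -0.36 in dcp5-1 at T0, and -0.08 and -0.18 at T15, and that of 864 long noncoding RNAs was -0.15 and -0.17 at T0, and -0.03 and -0.07 at T15. For 110 other noncoding RNAs it was -0.33 and -0.19 at T0, and 0.33 and 0.04 at T15, and for 25 microRNA genes it was -0.53 in Col-0 at T0 and 0 in the other groups. No test was made between these classes. Chloroplast-encoded genes stayed low in the polysomal columns, at -0.62 in Col-0 and -0.46 in dcp5-1 at T15.

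The following test was fixed before the result was seen. A difference between the genotypes already present before NaCl may account for the genes that responded differently in total RNA, since a gene that starts lower has more room to rise. The rank correlation of the difference in response with the T0 genotype difference in polysomal RNA was -0.10573, so that this explanation cannot be told apart from its absence. The polysomal libraries are not shared with the difference in response, but both fractions were taken from each lysate. A deviation of the T0 seedlings would thus enter both quantities with opposite sign. Several lists called for the difference in response had opposite medians in these 2 comparisons. At T0 in polysomal RNA, rapid regulators, photosynthesis genes, the seed list and heat shock genes had medians of -0.48, -0.73, -1.50 and 0.87. For the difference in response they had 0.40, 0.51, 0.72 and -0.33. The ABA, root-expressed and aquaporin lists also had opposite signs, and the ribosomal protein and translation factor lists the same sign. WRKY33, lower in dcp5-1 total RNA at T0 (-1.41), rose there under NaCl (1.15). Both of these values use the same dcp5-1 total RNA libraries at T0, so a low reading in them would give both. Time points after 15 min would help to separate a delayed response from a different one, and a second mutant allele would test whether the difference belongs to DCP5.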
